A study of Mus musculus with 15 samples.

How the data were processed

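Poly-A-selected RNA was sequenced from the ipsilateral basal ganglia of 15 mice, with 1 library per mouse and 5 mice in each of 3 groups: sham surgery, intracerebral haemorrhage (ICH), and ICH treated with Nao Yi Kang decoction (NYKD). The design text calls the treated group NYKD-M, and the sources used here do not say what the M stands for. Tissue was taken on day 3 after saline perfusion. The deposited table holds counts per Ensembl gene, 1 column per mouse, with no normalisation. HISAT2 2.0.5, edgeR 3.22.5 and the mm10 genome build are named per the submitters' processing notes, without their roles. The counting program, the annotation release and the strandedness are not given in the sources used here.

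The table had 54532 genes, of which 18725 had no count in any library. Library totals ran from 13539203 to 19909140 counts. Symbols, biotypes, coordinates, GC content and transcript lengths came from GENCODE mouse release M21. A symbol was found for 54409 genes. The other 123 genes held 0.0306% of all counts and were tested like the rest.

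Groups were taken from the sample titles. Genes were filtered with filterByExpr on the group, which kept 18052 genes, and library sizes were scaled by TMM. All 15 libraries entered 1 edgeR 4.0.16 model with a coefficient per group and no covariate, fitted by quasi-likelihood with robust dispersions (R 4.3.3). The quasi-likelihood F-test was made for ICH against sham, NYKD against ICH and NYKD against sham. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Adjusted p values for genes come from this model unless another tool is named. Log2 fold changes followed by ± carry a standard error (SE). It was derived as the absolute log2 fold change over the square root of the F statistic, so it is approximate. Expression levels are TMM-scaled CPM, with means and standard deviations (SD) over 5 libraries per group.

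There were 37 gene lists of cell types and pathways, fixed from textbook knowledge before the data were examined, as were the comparisons, tests, rule for named genes and most of the other settings. For each list, members called over all genes were counted, and again with the p values adjusted over the list alone. Only members among the tested genes entered these counts and their totals. Each list was compared with all other tested genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera was then run with the correlation estimated from the data. The fry test, which asks whether the members moved 1 way on balance, was an alternative. List p values were adjusted over the 37 lists. Library measures and list means per library were compared between groups with two-sided exact permutation tests, whose smallest possible p at 5 against 5 is 0.00794, and were adjusted over the 6 library measures or the 37 lists of a comparison.

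Named genes followed 4 rules. The first took up to 10 raised and 10 lowered genes per comparison with the largest fold changes. These genes needed an adjusted p under 0.05, a mean of at least 50 counts per library in the higher group, no overlap between the libraries of the 2 groups, and a symbol that was not a clone or predicted model. The second took up to 4 members per list with the smallest p, whether or not they passed. The third was a fixed set of 11 genes: Hmox1, Gfap, Il1b, Lcn2, Spp1, P2ry12, Ppp1r1b, Drd2, Mbp, Cldn5 and Gpx4. The fourth took the 10 strongest genes of the set that ICH and NYKD changed in opposite directions. Some genes that these rules name are not reported here.

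The ICH libraries enter both the ICH against sham and the NYKD against ICH comparison. The chance number of opposite genes came from the product of the 2 lists, which ignores this sharing. For the correlation across all genes, 20 simulated data sets with unchanged groups gave the value from sharing alone. In addition, the ICH libraries were split 20 times so that no library entered both comparisons.

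Other settings, also fixed before the data were examined, were RLE size factors, scaling by library totals, no count filter, a minimum of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, non-robust dispersions, a fit of 2 groups only, a replicate block, protein-coding genes only, omission of hemoglobin and mitochondrial genes, stricter thresholds, and the omission of each library in turn. A correction for GC content and transcript length (a spline with 5 degrees of freedom per library), NYKD against sham without ICH replicate 4, and list tests with an estimated correlation without that library, were chosen after seeing the data.

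The calling was tested on simulated data, with negative binomial counts at the estimated dispersions and changes seeded into genes with a mean of at least 50 counts. In the NYKD against ICH comparison, 54 of 100 genes seeded at a log2 change of 1 and 95 of 100 at 2 were recovered, with 9 false calls among 17733 genes. In NYKD against sham, 52 and 93 of 100 were recovered, with 2 false calls. With no change seeded between ICH and sham, 0 genes were called.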

Results

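Gene expression was measured by poly-A RNA sequencing in the ipsilateral basal ganglia of 15 mice, 3 days after surgery. Of these, 5 had sham surgery, 5 had ICH, and 5 had ICH followed by NYKD, a decoction given by oral gavage at 5.79 g/kg once per day for 3 days. Sham and ICH mice received distilled water. Libraries held 13539203 to 19909140 counts, a depth at which 18052 genes could be tested. Correlations between libraries ran from 0.870 to 0.981, computed across genes, which are not independent replicates. ICH replicate 4 had the smallest total.

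The comparison of ICH with sham asked what the haemorrhage changed in the tissue around it. On day 3, most listed genes of reactive astrocytes, dividing cells, phagocytes, complement and matrix remodelling rose, and some synaptic and neurofilament genes fell. As lists, the raised groups did not pass with an estimated correlation (adjusted p from 0.0537 to 0.232). Their list means per library were higher after ICH by exact permutation tests. The adjusted p was 0.01835 for reactive astrocytes, phagocytic genes, complement and matrix proteases, and 0.04195 for the cell cycle. Gfap, the intermediate filament of astrocytes (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912, mm10), averaged 3273 ± 361 CPM after ICH and 952 ± 401 in sham (SD, n = 5 per group). Its log2 fold change was 1.78 ± 0.26 (SE; adjusted p = 0.000313). Hmox1, which encodes the heme-degrading enzyme heme oxygenase-1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), rose from 144 ± 109 to 754 ± 241 CPM, a log2 fold change of 2.38 ± 0.58 (adjusted p = 0.0112). In all, 3062 genes changed, 2236 raised and 826 lowered, and 1553 of them by at least 2-fold (1402 raised, 151 lowered). Raised genes were 73.02% of the calls with TMM, 64.18% with RLE size factors and 83.4% with library totals, which shifted the median of all genes by 0.0954 on the log2 scale. The omission of ICH replicate 4, described below, gave 3270 genes (2326 raised, 944 lowered), and 2653 of the 3062 genes kept their call. That was the highest count with 1 library left out. The lowest were 2127 without sham replicate 3 (1623 raised, 504 lowered) and 2188 without ICH replicate 3 (1692 raised, 496 lowered).

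Reactive astrocyte genes rose in 16 of 16 cases, also when adjusted over the list alone, with a median log2 fold change of 2.70 (camera adjusted p = 5.76e-17, adjusted p = 0.0537 with an estimated correlation). Among them were Vim, an intermediate filament gene (3.18 ± 0.33, adjusted p = 2.87e-05), and Osmr, the oncostatin M receptor (2.72 ± 0.24, adjusted p = 8.99e-06). Lcn2, an iron-carrier-binding protein made by reactive glia and neutrophils, rose by 4.80 ± 0.77 (adjusted p = 0.000779), and by 3.59 without ICH replicate 4 (adjusted p = 0.000326). Of 12 homeostatic astrocyte genes, 1 rose and 2 fell (2 and 3 over the list alone, camera adjusted p = 0.222). The riser was Aldh1l1 (0.89 ± 0.17, adjusted p = 0.00216), an astrocyte folate enzyme. The 2 lowered members, Aldoc and Ntsr2, lost their calls on the omission of any of several single libraries, with adjusted p up to 0.0907 and 0.0766. All 18 cell cycle genes rose, over all genes and over the list alone, with a median of 2.63 (camera adjusted p = 5.74e-11, adjusted p = 0.232 with an estimated correlation). The cell cycle list mean of ICH replicate 4 was 2.31, against 4.19 to 5.60 in the other ICH libraries. Aurkb, a mitotic kinase, rose by 2.81 ± 0.40 (adjusted p = 0.000249), and Rrm2, which makes deoxynucleotides, by 2.65 ± 0.42 (adjusted p = 0.000568).

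Phagocytic and lipid-handling genes of microglia and macrophages rose in 15 of 18 cases (17 over the list alone, median 1.46, camera adjusted p = 2.55e-08, adjusted p = 0.232 with an estimated correlation). Examples were the lysosomal membrane gene Cd68 (2.17 ± 0.32, adjusted p = 0.000332) and the lysosomal protease gene Ctsb (1.28 ± 0.22, adjusted p = 0.00084). Spp1, the secreted phosphoprotein osteopontin, was a member without a call (2.16 ± 0.77, adjusted p = 0.0650), and passed without ICH replicate 4 (2.46, adjusted p = 0.0285). Homeostatic microglia genes rose in 6 of 13 cases (7 over the list alone, median 0.78, camera adjusted p = 0.0754, adjusted p = 0.640 with an estimated correlation). With ICH replicate 4 left out, 8 rose (camera adjusted p = 2.14e-05, adjusted p = 0.281 with an estimated correlation), and without sham replicate 3 or sham replicate 5, 3 rose. Csf1r, the receptor that microglia need for survival, rose by 0.88 ± 0.18 (adjusted p = 0.00295), while the purinergic receptor gene P2ry12 had no call (0.14 ± 0.29, adjusted p = 0.789). Complement genes rose in 11 of 12 cases, over the list alone as well, with a median of 1.79 (camera adjusted p = 4.90e-10, adjusted p = 0.0537 with an estimated correlation). The C1 inhibitor gene Serping1 rose by 1.98 ± 0.16 (adjusted p = 4.6e-06), and C3, the central complement component, by 4.11 ± 0.47 (adjusted p = 8.05e-05).

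Genes of recruited and border-associated myeloid cells were higher as well. Border-associated macrophage genes rose in 7 of 8 cases (7 over the list alone, median 2.75, camera adjusted p = 5.84e-07, adjusted p = 0.0537 with an estimated correlation), among them the coagulation factor gene F13a1 (4.04 ± 0.44, adjusted p = 5.02e-05). Monocyte and macrophage genes rose in 8 of 10 cases (10 over the list alone, median 3.21, camera adjusted p = 9.21e-07, adjusted p = 0.146 with an estimated correlation). Arg1, an arginine-degrading enzyme of wound macrophages, averaged 119 ± 22.6 CPM after ICH and 3.03 ± 2.84 in sham (log2 fold change 5.30 ± 0.64, adjusted p = 0.000111). Neutrophil genes rose in 6 of 6 cases, over the list alone as well, with a median of 5.25 (camera adjusted p = 0.000578, adjusted p = 0.236 with an estimated correlation). That size came from 1 library: the neutrophil list mean was 6.03 on the log2 CPM scale in ICH replicate 4 and 1.11 to 1.80 in the other 4 ICH libraries, and without it 4 members rose with a median of 1.59. Inflammatory cytokines and chemokines followed the same library. Of 15, 13 rose (15 over the list alone, median 3.18, camera adjusted p = 9.21e-07, adjusted p = 0.252 with an estimated correlation), and 8 rose without ICH replicate 4, with a median of 1.57. Ccl2, which attracts monocytes, rose by 3.67 ± 0.68 (adjusted p = 0.00201). The call of Il1b, the interleukin-1 beta gene, rested on that library, with a log2 fold change of 6.12 ± 1.61 (adjusted p = 0.0171) with it and 1.17 without it (adjusted p = 0.200).

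Of the 10 raised genes with the largest fold changes, Saa3, an acute-phase protein gene, led with 10.88 ± 2.11 (adjusted p = 0.00289). It rose by 5.63 without ICH replicate 4 (adjusted p = 1.86e-05). Of the 20 genes named for the largest changes in this comparison, raised and lowered, 1 lost its call without that library. The neutrophil chemokine gene Cxcl1 rose by 6.15 and by 3.27 without that library, the clotting factor gene F10 by 5.86 and 2.51, the chitinase-like gene Chil3 by 5.60 and 2.51, and the protease inhibitor gene Slpi by 5.23 and 1.80. Mmp3, a matrix protease gene, rose by 5.84 and 3.55. Trem1, a myeloid receptor gene, rose by 5.45 and 3.71, and the serine protease inhibitor gene Serpina3m by 5.15 and 4.34. The 10 raised genes were chosen with ICH replicate 4 included, and the count minimum was not re-applied without it. The other 4 ICH libraries averaged 0.94 CPM for the neutrophil gene Cxcr2, 1.09 for Mmp3, 1.54 for Trem1 and 1.76 for Slpi. They averaged 1.99 for F10, 2.27 for Cxcl1 and 2.415 for Serpina3m. In ICH replicate 4 these were at 11.31 to 94.28 CPM. Without it their adjusted p was 0.000434 to 0.0124. Saa3, Chil3 and Arg1 averaged 10.64, 4.77 and 113.9 CPM in the other 4. NF-kB and Toll-like receptor genes rose in 12 of 14 cases (14 over the list alone, median 2.37, camera adjusted p = 8.57e-08, adjusted p = 0.232 with an estimated correlation), with a median of 1.35 without ICH replicate 4. Among them, the receptor gene Tlr2 rose by 2.73 ± 0.41 (adjusted p = 0.000451) and the adaptor gene Myd88 by 1.54 ± 0.24 (adjusted p = 0.000421). Inflammasome and pyroptosis genes rose in 8 of 10 cases, over the list alone as well (median 1.64, camera adjusted p = 4.13e-05, adjusted p = 0.146 with an estimated correlation), including the pore-forming Gsdmd (1.47 ± 0.30, adjusted p = 0.00289). Antigen presentation genes rose in 9 of 12 cases (11 over the list alone, median 1.43, camera adjusted p = 2.42e-05, adjusted p = 0.236 with an estimated correlation). Interferon-stimulated genes rose in 6 of 15 cases (13 over the list alone, median 1.07, camera adjusted p = 2.42e-05, adjusted p = 0.311 with an estimated correlation). That count was 3 without ICH replicate 3, sham replicate 3 or sham replicate 5, and 11 without sham replicate 1.

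Heme and iron genes rose in 9 of 15 cases and 1 fell (11 and 1 over the list alone, median 0.93, camera adjusted p = 0.000651, adjusted p = 0.146 with an estimated correlation), and 5 rose without sham replicate 3 or sham replicate 4. The 1 lowered member lost its call without ICH replicate 2 or 5 or sham replicate 1, 3 or 4. Besides Hmox1, these included the ferritin light chain gene Ftl1 (1.55 ± 0.34, adjusted p = 0.00503) and the phagosomal metal transporter gene Slc11a1 (2.36 ± 0.36, adjusted p = 0.000447). Ferroptosis and NRF2 genes rose in 8 of 15 cases (9 raised and 1 lowered over the list alone, median 0.47, camera adjusted p = 0.00184, adjusted p = 0.112 with an estimated correlation). The transcription factor gene Nfe2l2 itself rose by 1.44 ± 0.16 (adjusted p = 4.49e-05), while Gpx4, the lipid peroxide reductase that guards against ferroptosis, had no call (-0.24 ± 0.16, adjusted p = 0.327). Apoptosis and p53 genes rose in 6 of 14 cases (7 over the list alone, median 0.54, camera adjusted p = 0.00554, adjusted p = 0.232 with an estimated correlation), led by the initiator caspase gene Casp8 (1.93 ± 0.28, adjusted p = 0.000311).

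In the vessels and matrix, proteases and their inhibitors rose in 10 of 12 cases (11 over the list alone, median 2.15, camera adjusted p = 2.00e-06, adjusted p = 0.146 with an estimated correlation). Adamts1, a secreted matrix protease gene, rose by 1.87 ± 0.24 (adjusted p = 0.000111). Pericyte, fibroblast and collagen genes rose in 7 of 14 cases (10 over the list alone, median 1.32, camera adjusted p = 0.0011, adjusted p = 0.264 with an estimated correlation), and in 4 without ICH replicate 3. Fn1, which encodes fibronectin, rose by 1.67 ± 0.29 (adjusted p = 0.000883). Endothelial and blood-brain barrier genes rose in 4 of 12 cases (5 over the list alone, median 0.14, camera adjusted p = 0.127), including the tight junction gene Cldn5 (0.79 ± 0.21, adjusted p = 0.0158). Endothelial activation genes rose in 6 of 8 cases, over the list alone as well (median 1.48, camera adjusted p = 0.00451, adjusted p = 0.232 with an estimated correlation), but in 3 without ICH replicate 4, sham replicate 3 or sham replicate 5. The adhesion molecule gene Vcam1 rose by 1.30 ± 0.20 (adjusted p = 0.000421).

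Among neuronal genes, 4 of 18 pan-neuronal and synaptic members fell (7 over the list alone, median -0.66, camera adjusted p = 8.08e-06, adjusted p = 0.232 with an estimated correlation). That count was 7 without ICH replicate 4 and 2 without sham replicate 2. They included Syp, a synaptic vesicle protein gene (-0.82 ± 0.21, adjusted p = 0.0136). Of 16 striatal projection neuron genes, 0 were called by edgeR over all genes or over the list alone (median -1.04, camera adjusted p = 0.0011, adjusted p = 0.505 with an estimated correlation), and 2 fell without sham replicate 1. The striatal list mean of sham replicate 1 was 5.93, against 8.14 to 8.56 in the other 4 sham libraries. Ppp1r1b, the dopamine-regulated phosphoprotein DARPP-32, had a log2 fold change of -0.94 ± 0.78 (adjusted p = 0.443), and the dopamine receptor gene Drd2 -0.98 ± 0.55 (adjusted p = 0.240). Myelin genes fell in 2 of 12 cases (2 over the list alone, median -0.45, camera adjusted p = 0.000779, adjusted p = 0.387 with an estimated correlation), and in 4 without ICH replicate 2. The median of that list was -0.20 without ICH replicate 4, where 2 fell (camera adjusted p = 0.0206, adjusted p = 0.491 with an estimated correlation). Opalin, an oligodendrocyte membrane protein gene, fell by 0.97, and Mbp, the myelin basic protein gene, had no call (-0.70 ± 0.32, adjusted p = 0.143). Genes of the respiratory chain fell in 4 of 12 cases (10 over the list alone, median -0.36, camera adjusted p = 1.64e-05, adjusted p = 0.236 with an estimated correlation). That count ran from 1 without sham replicate 3 to 7 without sham replicate 4, and was 2 without ICH replicate 3, 4 or 5 or sham replicate 1 or 2. The lowered genes with the largest fold changes included Mafa, a transcription factor gene (-3.08 ± 0.59, adjusted p = 0.00196), Gdf10, a growth factor gene (-1.91 ± 0.38, adjusted p = 0.00236), and the activity-regulated gene Arc (-1.81 ± 0.30, adjusted p = 0.000852). Cplx3, a synaptic complexin gene, fell by 1.78, and Hhip, a hedgehog-binding protein gene, by 1.56.

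**Figure D1:**
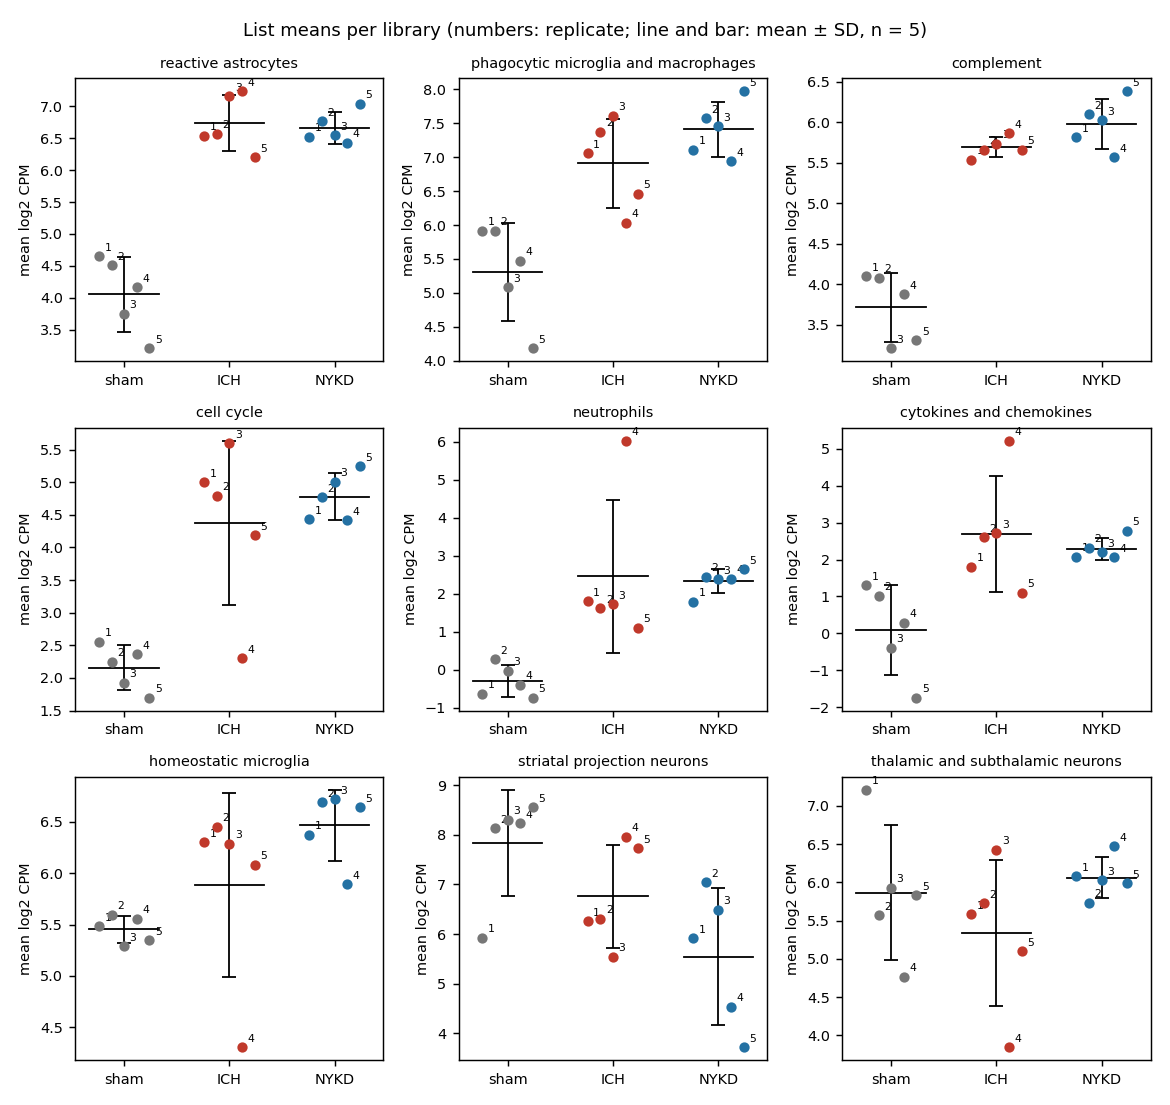
Mean log2 CPM of 9 of the gene lists in each library, by group (points with replicate numbers, line and bar for mean ± SD, n = 5 per group). The reactive astrocyte means of the ICH and NYKD libraries all lie above the highest sham value of 4.65, and ICH replicate 4 stands apart with a neutrophil mean of 6.03.

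The comparison of NYKD with ICH asked what the decoction changed after haemorrhage. A moderate set of genes differed, and 6 of them belonged to the fixed lists, none of these to the cytokine, NF-kB, inflammasome, interferon or complement lists. With 625 of 18052 tested genes called, lists of this size would hold few calls by chance, so that absence says little. At that share the 37 lists together would hold more than 6 calls, so these members are no excess over all genes. Hipk2, a stress-responsive kinase gene (ENSMUSG00000061436, chromosome 6, 38694390 to 38876165, mm10), averaged 197 ± 24 CPM with NYKD and 64.6 ± 37.4 after ICH (SD, n = 5 per group), a log2 fold change of 1.61 ± 0.34 (adjusted p = 0.0315). Lrp1, a scavenger receptor that takes up heme-hemopexin complexes (ENSMUSG00000040249, chromosome 10, 127538161 to 127621148), averaged 1367 ± 294 and 649 ± 122 CPM (1.08 ± 0.19, adjusted p = 0.0298). Rgs11, a regulator of G protein signalling, fell from 32.5 ± 18.5 to 7.36 ± 1.79 CPM (-2.14 ± 0.42, adjusted p = 0.0315). In all, 625 genes changed, 215 raised and 410 lowered, and 284 of them by at least 2-fold (51 raised, 233 lowered). Raised genes were 34.4% of the calls with TMM, 41.34% with RLE size factors and 20.14% with library totals, which shifted the median of all genes by -0.0768. At an adjusted p under 0.01, edgeR called 0 genes, with 4185 at an unadjusted p under 0.05, while at an adjusted p under 0.05 DESeq2 called 1833 and limma-voom 446.

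The calls depended on single libraries. Without ICH replicate 4 the count was 1, and without ICH replicate 5 it was 0 (3499 genes at an unadjusted p under 0.05). It was 0 without NYKD replicate 1, 3 or 5 (3866, 3607 and 3541 genes unadjusted), 9 without NYKD replicate 4 and 279 without NYKD replicate 2. Without ICH replicate 1 it was 1508, without ICH replicate 2 it was 363, and without ICH replicate 3 it was 314. The genes named for this comparison were on the edge of the threshold: all lost their call without ICH replicate 4, at adjusted p of 0.0602 or above. With that library left out, the log2 fold change of Ptger3 was 2.02, that of Nxpe5 1.85, Gucy1a2 1.75, Nt5c1a 1.61, Nynrin 1.40, Ptchd4 1.43, Soga1 1.29, Dusp4 1.57 and Emilin1 1.30. Of the lowered genes, Muc3a was then at -2.41, Rnf207 at -2.08, Thpo at -1.59, Grin1os at -1.65, C78859 at -1.85, Tgfbr3l at -1.58, Mir5125 at -1.89 and Tmc4 at -1.74. The other raised genes with the largest changes were Ptger3, a prostaglandin E2 receptor gene (2.03 ± 0.45, adjusted p = 0.0319), Nxpe5 (1.88), Gucy1a2, a subunit of the nitric oxide receptor (1.78), and Nt5c1a, a nucleotidase gene (1.70). Nynrin (1.54), Ptchd4 (1.40), Soga1 (1.40), the phosphatase gene Dusp4 (1.31) and the elastic fibre gene Emilin1 (1.28) completed the 10. The lowered genes were led by Wnt10b, a Wnt ligand gene (-3.88 ± 0.97, adjusted p = 0.0429; -1.89 and adjusted p = 0.121 without ICH replicate 4). Next came the mucin gene Muc3a (-3.01), Rnf207 (-2.40) and Thpo, the thrombopoietin gene (-2.18). Grin1os (-2.14), C78859 (-2.11), Tgfbr3l (-2.04), Mir5125 (-1.94) and Tmc4 (-1.92) followed.

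Of the list members, 6 were called over all genes. Those raised included Slc4a4, an astrocyte bicarbonate transporter gene (0.67 ± 0.15, adjusted p = 0.0323), Lrp1 and Fn1 (1.27 ± 0.28, adjusted p = 0.0323). Those lowered were the activity-regulated Npas4 (-1.26 ± 0.31, adjusted p = 0.0396) and the clock gene Per3 (-1.09 ± 0.26, adjusted p = 0.0360). All 6 lost their call without ICH replicate 4 (adjusted p from 0.0602 to 0.0787). The separate set of 11 genes named in advance had no call. Gfap differed by 0.21 ± 0.25 (adjusted p = 0.661), and Hmox1 by 0.65 ± 0.56 (adjusted p = 0.514), at 1185 ± 255 CPM with NYKD and 754 ± 241 after ICH. Il1b differed by -3.72 ± 1.36 (adjusted p = 0.121), and by 1.23 without ICH replicate 4 (adjusted p = 0.25). Lcn2 differed by -1.16 ± 0.66 (adjusted p = 0.314), and by 0.06 without that library. Spp1 (0.72 ± 0.74), P2ry12 (0.25 ± 0.29), Ppp1r1b (-1.49 ± 0.79), Drd2 (-1.01 ± 0.55), Mbp (0.18 ± 0.32), Cldn5 (-0.08 ± 0.21) and Gpx4 (-0.11 ± 0.16) had adjusted p from 0.278 to 0.862.

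As groups, 12 of the 37 lists differed by camera, but with an estimated correlation none did (adjusted p = 0.801 or above), nor by the directional fry test (adjusted p of at least 0.202). Striatal projection neuron genes were lower, with a median of -1.02 (camera adjusted p = 0.00308, adjusted p = 0.807 with an estimated correlation), and 0 of 16 members called by edgeR. That median was -0.68 without ICH replicate 4. List means were 4.54 and 3.72 in NYKD replicates 4 and 5, 5.92 to 7.05 in the other NYKD libraries and 5.54 to 7.96 after ICH. Genes of the neighbouring thalamus and subthalamus pointed the other way, without a call (median 0.35, camera adjusted p = 0.0851). Higher by camera were homeostatic astrocytes (median 0.39, adjusted p = 0.00308, but 0.25 and 0.0223 without ICH replicate 4), pericytes and collagen matrix (median 0.50, adjusted p = 0.00321, with a list mean of 7.40 in NYKD replicate 5 and 6.08 to 6.46 in the other NYKD libraries, and a median of 0.26 without it), homeostatic microglia (median 0.41, adjusted p = 0.00722), oligodendrocyte precursors (median 0.42, adjusted p = 0.00722) and endothelium (median 0.36, adjusted p = 0.0158). Their adjusted p with an estimated correlation was 0.801 for homeostatic astrocytes, pericytes and endothelium, and 0.807 for homeostatic microglia and oligodendrocyte precursors. Of 12 endothelial genes, 0 were called over all genes and 5 rose when adjusted over the list alone. Phagocytic genes (median 0.36, camera adjusted p = 0.0273), border-associated macrophages (median 0.51, adjusted p = 0.0429) and matrix proteases (median 0.46, adjusted p = 0.0429) had adjusted p of 0.807, 0.801 and 0.807 with an estimated correlation. Camera's call was lost for phagocytic genes without NYKD replicate 2 or 5 or ICH replicate 1, 4 or 5 (adjusted p up to 0.132). It was lost for border-associated macrophages without NYKD replicate 2, 3 or 5 or ICH replicate 1, 2 or 5 (up to 0.138), and for matrix proteases without NYKD replicate 2, 3 or 5 or ICH replicate 1 or 5 (up to 0.196). Without ICH replicate 4, whose homeostatic microglia mean of 4.31 and oligodendrocyte precursor mean of 4.34 were the lowest of all libraries of its group, the median was 0.25 for homeostatic microglia (camera adjusted p = 0.0946), 0.17 for oligodendrocyte precursors (adjusted p = 0.0504) and 0.26 for phagocytic genes (adjusted p = 0.118). Reactive astrocytes (median -0.24, camera adjusted p = 0.829), cytokines (median -0.97, adjusted p = 0.407), NF-kB genes (median -0.65, adjusted p = 0.348), inflammasome genes (median -0.42, adjusted p = 0.519) and neutrophils (median -1.60, adjusted p = 0.831) did not pass. These lower medians came from 1 library: without ICH replicate 4 they were 0.06, 0.08, 0.16 and -0.06 for the first 4 lists, still without a call, and the neutrophil list pointed up with NYKD (median 0.98, camera adjusted p = 0.0344), with 0 of 6 members called by edgeR. With an estimated correlation no list passed without that library either (adjusted p of at least 0.678). Heme and iron genes, with 1 of 15 raised, had a median of -0.02 and a mean of -0.23 although camera pointed up (adjusted p = 0.519), and a median of 0.16 with that library left out. Endothelial activation genes likewise had a median of -0.02 and a mean of -0.24 with camera up (adjusted p = 0.348), and a median of 0.53 without ICH replicate 4 (adjusted p = 0.0496). Monocyte genes had a median of 0.54 and a mean of -0.03 (camera adjusted p = 0.135, or a median of 0.74 and adjusted p = 0.0344 without ICH replicate 4), and growth factor genes a median of -0.06 and a mean of 0.04 (camera adjusted p = 0.519, or a median of 0.19 without that library).

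The lowered genes were rich in non-coding genes. Non-coding genes made up 30.7% of the lowered calls, 2.82% of the raised calls and 16.4% of the genes tested. After the correction for GC content and transcript length their share of the lowered calls was 17.9%, near that of all genes tested. The lowered coding calls grew with it, from 284 of 410 to 552 of 672, so the share fell without a like loss of non-coding calls. Their share of all counts was 1.68 ± 0.146% with NYKD and 2.42 ± 0.204% after ICH (SD, n = 5; exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0476), with no overlap between the groups. In sham it was 2.17 ± 0.335%. With protein-coding genes alone, 365 genes changed (117 raised, 248 lowered).

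**Figure D2:**
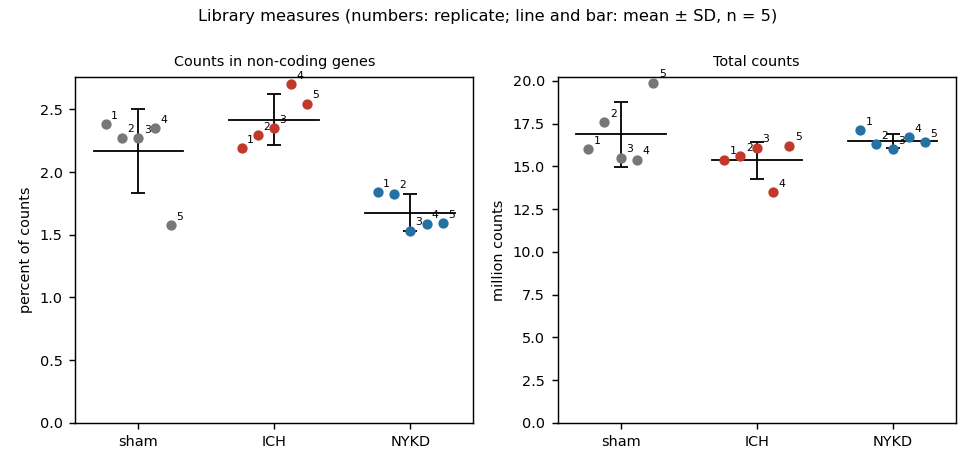
Percent of counts in non-coding genes (left) and total counts (right) for each library, by group (points with replicate numbers, line and bar for mean ± SD, n = 5). NYKD libraries averaged 1.68% non-coding counts, below the 2.42% of the ICH libraries.

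The next question was which genes changed by ICH moved the other way with NYKD. There were 86, of which 53 were lowered by ICH and raised with NYKD and 33 went the other way. This split depended on the scaling: it was 75 and 24 with RLE size factors, and 27 and 53 with library totals. Rims3, a presynaptic scaffold gene, fell by 1.17 after ICH and rose by 1.25 with NYKD, from 202 ± 71.9 CPM in sham to 89.5 ± 24.9 after ICH and 212 ± 53.7 with NYKD (SD, n = 5 per group). Ctif, a translation factor gene, changed by -0.69 and 0.84, Mgat3, a glycosyltransferase gene, by -0.74 and 0.56, and Tmem151b by -1.46 and 1.02. Ptchd4 changed by -1.43 and 1.40, Tmem229b by -0.55 and 0.57, the phosphatase gene Dusp3 by -0.56 and 0.58, and 6430548M08Rik by -0.77 and 0.74. Pan3, a subunit of a poly(A)-shortening complex, rose by 0.61 after ICH and fell by 0.65 with NYKD. If the calls were independent, 60.6 opposite genes would arise: 9.84 lowered then raised, against 53, and 50.8 raised then lowered, against 33. These values hold for TMM scaling and ignore that both comparisons use the ICH libraries. A further 24 genes were raised in both comparisons (26.6 by chance) and 0 were lowered in both (18.8 by chance).

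Across all genes, the slope of the NYKD effect on the ICH effect was -0.174 and the correlation -0.229. Sharing the ICH libraries alone gave a mean correlation of -0.497 in simulated sets with unchanged groups. A correlation also depends on the spread of the real effects, which those sets lack. The covariance was -0.0999, against -0.0623 from sharing alone, a difference of -0.0376. The simulated sets gave each gene 1 dispersion for all groups. A wider spread among the ICH libraries would enlarge the part from sharing, so this difference cannot be read as opposition beyond sharing. In the 20 splits with no shared library, the median slope was -0.0190 (-0.132 to 0.232), the median covariance -0.0115 (-0.0691 to 0.153) and the median number of opposite calls 0 (0 to 85), at 2 or 3 ICH libraries per comparison. The split with 85 had 635 genes called in the same direction, and independent lists would give it 308 opposite ones. Genes are not independent replicates, and these values carry no test. The 86 genes became 252 without ICH replicate 1, 56 without sham replicate 5, 32 without ICH replicate 3, and 1 without ICH replicate 4 or NYKD replicate 4. They became 0 without ICH replicate 5 or NYKD replicate 1, 3 or 5, where edgeR called 0 genes between NYKD and ICH (3499 to 3866 at an unadjusted p under 0.05).

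The comparison of NYKD with sham asked what still differed from sham after the decoction. Most listed reactive astrocyte, phagocyte, complement and cell division genes stayed above sham, and 10 of 16 striatal projection neuron genes were below it. As lists, none of these passed with an estimated correlation (adjusted p from 0.0508 to 0.276). Gfap was higher by 1.99 ± 0.26 (adjusted p = 6.08e-05), Hmox1 by 3.04 ± 0.60 (adjusted p = 0.00214), Lcn2 by 3.65 ± 0.73 (adjusted p = 0.00240), Spp1 by 2.88 ± 0.79 (adjusted p = 0.0162) and Arg1 by 6.10 ± 0.66 (adjusted p = 1.98e-05). Drd2 (ENSMUSG00000032259, chromosome 9, 49340627 to 49408177, mm10) fell from 172 ± 77.2 CPM in sham to 43.3 ± 31.2 with NYKD (SD, n = 5 per group; -1.99 ± 0.56, adjusted p = 0.0195). In all, 4225 genes changed, 2766 raised and 1459 lowered, and 2140 of them by at least 2-fold (1595 raised, 545 lowered). Without NYKD replicate 5, 2810 changed (2131 raised, 679 lowered). The lowered genes were 801 without sham replicate 3, 887 without sham replicate 2 and 895 without NYKD replicate 3. With quality weights limma-voom called 8137.

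Most of the groups raised after ICH were also above sham with NYKD. Reactive astrocyte genes rose in 15 of 16 cases (16 over the list alone, median 2.71, camera adjusted p = 7.56e-14, adjusted p = 0.0737 with an estimated correlation), cell cycle genes in 18 of 18 (18 over the list alone, median 2.67, camera adjusted p = 6.93e-12, adjusted p = 0.190 with an estimated correlation) and phagocytic genes in 17 of 18 (17 over the list alone, median 2.01, camera adjusted p = 2.05e-10, adjusted p = 0.159 with an estimated correlation). Complement genes rose in 11 of 12 cases and border-associated macrophage genes in 7 of 8 (11 and 7 over the list alone, adjusted p = 0.0508 for both with an estimated correlation). Homeostatic microglia genes rose in 9 of 13 cases (9 over the list alone, median 0.94, camera adjusted p = 0.000217, adjusted p = 0.337 with an estimated correlation), with P2ry12 at 0.38 ± 0.29 (adjusted p = 0.366). Monocyte genes rose in 8 of 10 cases, antigen presentation genes in 11 of 12, matrix proteases in 11 of 12, pericyte and collagen genes in 10 of 14 and endothelial genes in 7 of 12. Over the list alone these were 10, 11, 11, 11 and 7, and the adjusted p with an estimated correlation was 0.149, 0.190, 0.110, 0.159 and 0.190. Ferroptosis and NRF2 genes rose in 8 of 15 cases (9 over the list alone, adjusted p = 0.0508 with an estimated correlation), with Gpx4 at -0.35 ± 0.16 (adjusted p = 0.118). Heme and iron genes rose in 6 of 15 cases and 1 fell (8 and 1 over the list alone, adjusted p = 0.159 with an estimated correlation).

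Cytokine, NF-kB and neutrophil calls rose in number when ICH replicate 4, which is in the shared fit but not in this comparison, was left out. Cytokine genes rose in 5 of 15 cases and in 10 without that library, NF-kB genes in 8 of 14 and 13, and neutrophil genes in 3 of 6 and 6. Over the list alone 6, 9 and 4 rose, and the adjusted p with an estimated correlation was 0.322, 0.276 and 0.276. NF-kB genes rose in 5 cases without NYKD replicate 5, sham replicate 3 or sham replicate 5. Il1b, Saa3 and Cxcl1 had no call (adjusted p = 0.286, 0.0648 and 0.0819) and passed without ICH replicate 4 (0.00562, 8.19e-06 and 0.00564). Of the genes that led the ICH comparison, Mafa (-2.37 ± 0.56, adjusted p = 0.00606), Arc (-1.55 ± 0.30, adjusted p = 0.00158) and Hhip (-1.14 ± 0.21, adjusted p = 0.000953) were also lower with NYKD than in sham. Ptchd4 was at -0.02 ± 0.29 (adjusted p = 0.963) and Tmem151b at -0.44 ± 0.21 (adjusted p = 0.146). Of those that led the NYKD comparison, Nxpe5 (4.35 ± 0.57, adjusted p = 5.31e-05), Emilin1 (2.98 ± 0.36, adjusted p = 2.75e-05), Nynrin (1.21 ± 0.28, adjusted p = 0.00543) and Soga1 (1.09 ± 0.25, adjusted p = 0.00550) were also above sham. Muc3a (-2.71 ± 0.68, adjusted p = 0.00971), Rnf207 (-1.77 ± 0.46, adjusted p = 0.0110) and Rgs11 (-1.67 ± 0.42, adjusted p = 0.00885) were below it.

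Striatal projection neuron genes fell in 10 of 16 cases, and in all 16 when adjusted over the list alone, with a median of -2.04 (camera adjusted p = 3.29e-07, adjusted p = 0.276 with an estimated correlation). Ppp1r1b had a log2 fold change of -2.43 ± 0.82 (adjusted p = 0.0434), a call lost without any 1 of 8 of the 10 libraries, NYKD replicate 2 and sham replicate 1 excepted (adjusted p up to 0.0964). Without sham replicate 1, the sham library with the lowest striatal mean, 14 members fell. The count was 5 without NYKD replicate 4 or NYKD replicate 5, 4 without sham replicate 3, and 6 without sham replicate 2, 4 or 5. List means per library were 3.72 to 7.05 with NYKD and 5.93 to 8.56 in sham (exact permutation p = 0.0238, adjusted p = 0.0315 over 37 lists). Pan-neuronal genes fell in 1 of 18 cases (0 over the list alone, median -0.43, camera adjusted p = 0.00254, adjusted p = 0.353 with an estimated correlation). Their count was 3 without NYKD replicate 4, sham replicate 1 or ICH replicate 4, and 0 without NYKD replicate 2, 3 or 5 or sham replicate 2, 3, 4 or 5. Thalamic and subthalamic genes, which mark the neighbouring tissue, were called in 0 of 8 cases by edgeR (median 0.04, camera adjusted p = 0.809). Cortical neuron genes, with 1 of 10 lowered, had a median of 0.21 and a mean of 0.26 while camera pointed down (adjusted p = 0.841). Genes of the respiratory chain fell in 5 of 12 cases (8 over the list alone, median -0.33, camera adjusted p = 0.000133, adjusted p = 0.276 with an estimated correlation). That count was 3 without NYKD replicate 2 or 5 or sham replicate 1, and 8 without sham replicate 4. Mbp was at -0.52 ± 0.32 (adjusted p = 0.247).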

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

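The tests of why ICH replicate 4 stood apart, those on the striatal genes, and the correction for GC content and transcript length were chosen only after the results were seen. The matched-gene test was added after that correction, with its bounds set before its own value was known, and the omission of each library from the comparisons it enters was fixed beforehand. Single libraries were compared with the other 4 of their group for 162 combinations of measure and group, and 18 lay apart. Chance alone would set apart about 1 in 20 groups.

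For the calls between NYKD and ICH, with non-coding genes among the lowered, chance is argued against but not excluded. Of 100 splits drawn from the 126 possible, the real one included, the real split gave 625 genes. The highest of the others drawn gave 30, and the splits not drawn are unknown. A GC or length bias as the whole source is argued against by the 529 of 625 calls that kept their direction after the correction. The non-coding part of the lowered calls went from 30.7% to 17.9%, near the 16.4% of all genes tested. That shift came with more lowered coding calls, 284 of 410 before and 552 of 672 after. It therefore says little about the non-coding calls themselves. For the 2943 non-coding genes as a class, coding genes matched on GC content, length and expression covered 39.3% of the way from all coding genes (95% interval 33.9 to 43.8), between the bounds set beforehand, so a bias stays open there. That interval came from resampling genes, not mice, so it leaves out the spread between libraries. Genes are not independent replicates, and the matches were 1460 distinct coding genes, many used more than once. More unspliced or nuclear RNA in the ICH than in the NYKD libraries may contribute, and the test does not tell which group departs. Of the lowered coding genes, 77.1% have an annotated retained-intron transcript, against 50.4% to 61.6% in random genes matched on expression only. After the correction these were 82.1% against 54.0% to 61.8%. The non-coding share of counts was 2.42% after ICH, 2.17% in sham (exact permutation p = 0.2143) and 1.68% with NYKD. Without ICH replicate 4, 1 of the 625 calls kept its direction, which met the condition set beforehand for that library as the source. With ICH replicate 5 or NYKD replicate 1, 3, 4 or 5 left out, 9 or fewer were kept as well. The omission of ICH replicate 1, 2 or 3 or NYKD replicate 2 kept 611, 329, 271 and 261. In all, 7 of the 9 other libraries, when left out, ended most of the calls. Neither this library as the source nor a loss of power is therefore settled, and an effect of the decoction stays open, untested.

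The second pattern is ICH replicate 4, far from the other 4 ICH libraries in neutrophil genes (6.03 on the log2 CPM scale against 1.11 to 1.80), NF-kB and Toll-like receptor genes (5.88 against 3.53 to 4.13), Il1b (6.80 against -0.87 to 0.27) and Lcn2 (10.39 against 7.14 to 8.04). It was low in homeostatic microglia (4.31 against 6.08 to 6.45), P2ry12 (3.98 against 5.82 to 6.32) and oligodendrocyte precursors (4.34 against 6.04 to 6.53). A sham library under an ICH label is argued against by its reactive astrocyte mean, 2.59 above the highest sham library. Residual blood is argued against by its hemoglobin share of 0.00175%, within the 0.000611% to 0.0025% of the other ICH libraries, and low depth by its neutrophil mean, still 4.22 above the highest other ICH library with all libraries thinned to 13539203 counts. A different stage or severity of the lesion in this mouse could give such values, as a hypothesis that no label here can test.

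The third pattern is the low striatal projection neuron genes with NYKD, against sham and, by camera alone, against ICH. Within groups, libraries low in striatal genes were high in thalamic and subthalamic genes (Pearson r = -0.696, permutation p = 0.00289; Spearman rho = -0.707, permutation p = 0.00422; 15 libraries), and r was -0.714 without sham replicate 1 and NYKD replicate 5 (permutation p = 0.00502). A different position of the tissue block may therefore move these genes between libraries, in sham replicate 1 as well. Sham replicate 1 and NYKD replicate 5 were left out for their striatal values alone. ICH replicate 4, with a striatal mean of 7.96 and a thalamic and subthalamic mean of 3.85, stayed in, and its omission was not tested. The correlation does not test the difference between groups. The mean of the thalamic and subthalamic list was 6.06 ± 0.267 with NYKD, 5.86 ± 0.882 in sham and 5.34 ± 0.959 after ICH (SD). In NYKD replicate 5, the library lowest in striatal genes (3.72), it was 5.99. A loss of neurons of every kind cannot be told apart with these samples: the striatal minus the pan-neuronal mean was -2.49 ± 1.36 with NYKD and -0.692 ± 0.895 in sham (SD, n = 5; two-sided exact permutation p = 0.0556). A loss of striatal neurons after haemorrhage stays open as well, untested.

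Chance is also argued against for ICH against sham, with 3062 genes in the real split. The highest other split of the 100 drawn gave 1638 and put sham replicate 1 with ICH replicates 1, 2, 3 and 5. The same holds for NYKD against sham, with 4225 genes and 400 in the highest other split drawn. In both, the rest of the 126 possible splits were not examined.

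Sham replicate 1 was far below the other 4 sham libraries in striatal projection neuron genes (5.93 against 8.14 to 8.56), Ppp1r1b (7.70 against 10.07 to 10.46), Drd2 (5.25 against 7.57 to 7.88) and circadian clock genes (5.53 against 6.07 to 6.12), on the log2 CPM scale. Sham replicate 5 had 22527 genes detected, against 24924 to 25695 in the other sham libraries, 1.58% of its counts in non-coding genes, against 2.27% to 2.38%, and P2ry12 at 6.0, against 5.61 to 5.72. NYKD replicate 1 was low in choroid plexus and ependyma genes (2.13 against 4.38 to 4.94). NYKD replicate 5 was high in pericyte, fibroblast and collagen genes (7.40 against 6.08 to 6.46) and low in immediate early genes (3.17 against 3.80 to 3.98). NYKD replicate 4 was low in Mbp (11.43 against 12.23 to 12.46).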

How the results depend on the processing

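The GC and length correction, NYKD against sham without ICH replicate 4, and list tests with an estimated correlation without that library were chosen after seeing the data. Under RLE size factors, library totals, no filter, a minimum of 1 CPM, limma-voom and non-robust dispersions, the counts of genes changed in the 3 comparisons stayed within 1.5 times. For NYKD against ICH, where the count was 625, DESeq2 called 1833, quality weights 1353, protein-coding genes only 365, and the GC and length correction 940. The stricter thresholds, which call fewer genes by construction, gave 284 (2-fold) and, with edgeR at an adjusted p under 0.01, 0 (4185 unadjusted). For ICH against sham they gave 1553 and 1488, and for NYKD against sham 2140 and 2106, while quality weights gave 8137. Leaving out each replicate in turn gave 0 to 1508 genes for NYKD against ICH (edgeR, 3499 to 4966 unadjusted), 2127 to 3270 for ICH against sham, 2810 to 4784 for NYKD against sham, and 0 to 252 for the 86 genes of the opposite set. That set held 325 genes with DESeq2, 137 with quality weights, 40 with 2 groups only, 159 with the GC and length correction, 15 at 2-fold and 0 at an adjusted p under 0.01. The slope of the NYKD effect on the ICH effect moved from -0.174 to -0.0190 with the ICH libraries split so that no library is shared. For the neutrophil list, NYKD against ICH reversed without ICH replicate 4, from lower (camera adjusted p = 0.831) to higher (0.0344, or 0.678 with an estimated correlation, with 0 of 6 members called by edgeR; 0.0344 to 0.958 over the libraries left out). The replicate numbers did not pair the samples: 4 of 15 same-numbered pairs correlated above 0.1 (-0.445 to 0.328, over 1000 genes). With the replicate number as a block, edgeR called 2255 genes for ICH against sham, 0 for NYKD against ICH (3602 unadjusted), 3278 for NYKD against sham and 0 in the opposite set. An estimated correlation ended 60 list calls, and as many without ICH replicate 4. Changes of sign of single genes between settings occurred in 42 cases where neither setting passed. Except for the thresholds, left-out libraries and unshared splits, the cause was not tested. In simulated data, 54 of 100 seeded log2 changes of 1 were recovered for NYKD against ICH. Those data held no deviating library, and only genes with a mean of at least 50 counts were seeded.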

Other observations

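Some growth factor, glucocorticoid-responsive, stress and immediate early genes changed after ICH, while none of these lists passed by camera. Of 11 growth factor genes, 3 rose after ICH, over the list alone as well (median 0.23, camera adjusted p = 0.204). They were Fgf2, a mitogen for glia and vessels (1.90 ± 0.21, adjusted p = 3.47e-05), Tgfb1, a regulator of scarring and immunity (1.53 ± 0.23, adjusted p = 0.000332), and Lif, an interleukin-6 family cytokine (3.76 ± 0.62, adjusted p = 0.000711; 2.52 without ICH replicate 4). Between NYKD and ICH, 0 of the 11 were called by edgeR, over all genes or over the list alone. Of 10 glucocorticoid-responsive genes, 3 rose after ICH (3 over the list alone), with a median of -0.04 and a mean of 0.25 (camera adjusted p = 0.704). The metallothionein genes Mt1 (1.49 ± 0.21, adjusted p = 0.000226) and Mt2 (1.58 ± 0.29, adjusted p = 0.00152), whose products bind zinc and copper, were among them, and with NYKD against ICH they had no call (-0.60 ± 0.20 and -0.67 ± 0.28, adjusted p = 0.0915 and 0.163). Of 14 endoplasmic reticulum and heat stress genes, 4 rose and 1 fell after ICH (5 and 1 over the list alone, camera adjusted p = 0.440), with the chaperone gene Hspa1b at 1.47 ± 0.28 (adjusted p = 0.00200). Of 13 immediate early genes, 3 rose and 1 fell (3 and 3 over the list alone, median -0.02, camera adjusted p = 0.490): Jun rose by 0.93 ± 0.15 and Fos by 1.07 ± 0.20, while Arc fell. Without ICH replicate 4, 4 of these genes fell and the median was -0.81, without sham replicate 1 it was 3, and without sham replicate 5 it was 2.

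By camera, cholesterol synthesis and erythroid genes were lower after ICH and higher with NYKD than after ICH. Clock genes were lower with NYKD, and none of these calls passed with an estimated correlation. Cholesterol synthesis genes fell in 3 of 14 cases after ICH, over the list alone as well (median -0.29, camera adjusted p = 0.00103, adjusted p = 0.320 with an estimated correlation). Insig1, which restrains sterol synthesis, changed by -0.89 ± 0.16 (adjusted p = 0.00107). With NYKD against ICH the list was higher by camera (median 0.23; adjusted p = 0.0429, adjusted p = 0.807 with an estimated correlation), a call lost without NYKD replicate 1, 4 or 5 or ICH replicate 1, 4 or 5 (adjusted p up to 0.335), with a median of 0.14 without ICH replicate 4. Erythroid genes were lower after ICH, with 1 of 5 called (3 over the list alone, median -1.16, camera adjusted p = 0.00898, adjusted p = 0.264 with an estimated correlation), and higher with NYKD than after ICH (median 0.83, camera adjusted p = 0.0317, adjusted p = 0.807 with an estimated correlation). The first call was lost without ICH replicate 1 or sham replicate 1, 2 or 5 (adjusted p up to 0.105), and the second without NYKD replicate 2 or ICH replicate 1 (up to 0.157). The hemoglobin gene Hbb-bt changed by -1.96 ± 0.51 after ICH (adjusted p = 0.0139), in tissue that had been perfused. Its counts were low: 0.85 CPM in ICH replicate 4, 0.41 on average in the other 4 ICH libraries and at most 3.885 in sham. Circadian clock genes had 0 of 12 calls after ICH by edgeR (median -0.16, camera adjusted p = 0.112, but 1 lowered, a median of -0.41 and adjusted p = 0.00553 without ICH replicate 4, where the adjusted p with an estimated correlation was 0.311, and 1 lowered and adjusted p = 0.0253 without sham replicate 1), 1 lowered with NYKD against ICH (2 over the list alone, median -0.55, camera adjusted p = 0.0110, adjusted p = 0.807 with an estimated correlation) and 5 lowered with NYKD against sham (5 over the list alone, median -0.58, camera adjusted p = 0.000491, adjusted p = 0.276 with an estimated correlation). The camera call against ICH was lost without NYKD replicate 5 or ICH replicate 4 (adjusted p up to 0.0702), with a median of -0.20 in the latter case, and 3 were lowered against sham without NYKD replicate 5.

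Markers of other cells and regions had few calls. After ICH, edgeR called 0 of 10 oligodendrocyte precursor genes (camera adjusted p = 0.569; 2 raised without ICH replicate 4, at a median of 0.27), 0 of 10 cortical neuron genes (0.190), 0 of 8 thalamic and subthalamic genes (0.142), 0 of 12 choroid plexus and ependyma genes (0.718) and 0 of 2 T, B and natural killer cell genes (0.944). Over all 18052 genes, 5617 had an unadjusted p under 0.05 in that comparison. Most members of the T, B and natural killer cell list were not among the tested genes. For the choroid plexus list the median was 0.34 and the mean 0.13 while camera pointed down, and for the precursors the median was 0.02 and the mean 0.09 while camera pointed down. Of 10 precursor genes, 3 rose with NYKD against sham (3 over the list alone, median 0.37, camera adjusted p = 0.0843), and 4 rose without ICH replicate 4 (camera adjusted p = 0.0111, adjusted p = 0.262 with an estimated correlation).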
